A study of Homo sapiens with 2 samples.

How the data were processed

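Single-cell RNA was measured in 2 samples of the human fibrosarcoma cell line HT1080, each a set of collagen-embedded spheroids after 72 h of invasion, without (control) or with (4B4) a β1 integrin-blocking antibody. Per the labels' protocols, gels were digested with collagenase and then trypsin, and libraries were made with the 10x Genomics Chromium 3′ kit, version 3. Groups were taken from the treatment labels. The deposited files hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 7.1.0, per the file headers. Per the submitters' processing notes the genome build was GRCh38, and Seurat 5.0.1 was also named, without its role. The gene annotation, any filter on barcodes beyond the cell calls, and the sequencing depth in reads are not given in the sources used here. Both files list the same genes, of which 10 symbols occur for more than 1 gene ID; such rows were kept apart by ID. The libraries shared 2 barcodes. No deposited cell annotation was used here.

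Barcodes with at least 1000 detected genes and at most 20% mitochondrially encoded UMIs were kept: 3402 of 3642 in the control library, with 127218114 UMIs, and 1385 of 1759 in the 4B4 library, with 116451080 UMIs. Counts were summed over kept cells and divided by the library total to give UMIs per 1000000 (UPM), and ratios are 4B4 over control on the log2 scale with no pseudocount. Sums carry exact Poisson intervals, ratios a Clopper-Pearson interval of the conditional binomial share, and shares of cells a Clopper-Pearson interval, at 95%. These intervals cover counting error only. With sums this large they are narrow and say nothing about variation between cultures, libraries or days. With 1 library per group no test, p-value or standard error was computed. A gene was counted by size alone: at least 20 UPM in either library and a ratio of at least 2.

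For comparisons of shares, phases and neighbours each cell was thinned without replacement to 17000 UMIs, the largest multiple of 1000 that at least 90% of kept cells reached in each library. This left out 303 control cells and 74 4B4 cells as too shallow. Phases were called on both libraries together with scanpy from 43 S genes and 54 G2M genes; the bound between G1 and the other phases is a score of 0, and cells near it were counted after the data had been seen. Scrublet, run in scanpy, marked 0 of 3402 and 2 of 1385 cells as doublets. That is too few for a usable call, since doublets of like cells are hard to see, so no cell was left out as a doublet and the alternative without the marked cells tests little.

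The 32 gene lists were fixed before the data were examined. There were 13 main lists (among them matrix metalloproteinases, other proteases, protease inhibitors, integrin subunits, focal adhesion, Rac and Arp2/3, collagens, other matrix proteins, mesenchymal factors, YAP and TEAD targets, SRF and MRTF targets, TGF-beta response) and background lists of cell cycle, stress, metabolic and signalling genes, epithelial markers, cell-cell adhesion and hyaluronan and other matrix receptors. Of the main lists 1 is not reported here, nor are some single genes. A member counted as measured at 5 UPM or more in either library. It was called higher or lower at a ratio of at least 1.5 with the counting interval on the same side of 1. A list's median was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. It is described as apart at or below percentile 2.5 and at or above 97.5. Some genes are on several lists. Genes were named by a rule also fixed beforehand: the 12 largest ratios in each direction at the floor of 20 UPM with the same sign under every alternative run for ratios, leaving out mitochondrially encoded, ribosomal protein and clone-named genes; up to 4 measured members of each list with the largest ratios; and a fixed set of adhesion, protease and cytoskeleton genes. MKI67, TOP2A, APOE, APOC1, LRRTM4, SGO1-AS1 and MALAT1 were named after their values were seen. Markers of other cell types were also fixed beforehand.

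Nearest neighbours were found in 30 principal components of 2000 highly variable genes, with 1311 cells drawn from each library. Leiden clustering at resolution 0.5 was run on each library alone with 15 neighbours. Clusters are called by number, and their leading genes are the largest ratios among genes of at least 50 UPM. Gene spans and positions came from GENCODE release 29 on GRCh38, joined by Ensembl gene ID, and 94.58% of gene IDs matched. Whether the authors used that release is not known, so these positions are those of the release named.

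Alternatives fixed before the data were examined were no cell filter, a stricter filter (at least 2000 genes and at most 10% mitochondrial UMIs), doublet calls left out, thinned cells, each cell weighing the same, TMM scaling from edgeR (factors 1.02 for the control and 0.984 for the 4B4 library), a total without mitochondrial and ribosomal protein genes, and the phases weighing the same. Counts were also made at a ratio of 1.5 and at floors of 5 and 50 UPM, and lists with 10 bins or a floor of 20. Chosen after seeing the data were cells of 20000 to 60000 UMIs, G1 cells only, removal of a running median over 200 genes ordered by gene span, and named gene ratios without the 1% of cells holding most of a gene. Values for G1 cells and equal phase weights use kept cells of at least 17000 UMIs with all their UMIs.

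The steps were tested on simulated data. With counts drawn from the control means at the depths of both libraries, 200 genes were given known folds among 6565 genes at the floor. The count at 2-fold found 33 of 33 genes at 2.5-fold higher, 33 of 33 at 4-fold higher, and 33 of 33 at each of the folds 0.25 and 0.4. It found none of 34 at each of the folds 0.8 and 1.25, and none of 6348 without a difference. These draws held counting error only. They do not show how many genes would be counted through variation between cultures or libraries. Ratio intervals covered the true value for 95.47% of 6556 genes. A list of 25 genes shifted by 0.3 had a median of 0.28 at percentile 100, and 4% of 200 lists without a shift were described as apart. Those 200 lists were random picks of genes that varied independently through counting error. The 4% is thus no error rate for lists whose genes move together between cultures or libraries. Software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.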

Results

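HT1080, an established human fibrosarcoma cell line that invades collagen with an elongated, protease-using shape, was grown as spheroids embedded in three-dimensional collagen gels. Spheroids were formed from 2000 cells each, about 50 of them were placed in 500 µl of collagen per sample, and cells were released after 72 h of invasion. The 4B4 culture received 2 µg/ml of an antibody that blocks β1 integrin, the subunit shared by the main collagen and fibronectin receptors, and the control culture did not. The control's treatment label names no other antibody, so blocking cannot be told apart from other effects of adding an antibody. Single-cell RNA was counted as unique molecular identifiers (UMIs), with 1 library per group. The control library held 128375944 UMIs in 3642 barcodes and the 4B4 library 119566832 UMIs in 1759 barcodes. After leaving out barcodes with fewer than 1000 detected genes or over 20% mitochondrial UMIs, 3402 control cells and 1385 4B4 cells were compared. Kept cells had a median of 32914 UMIs in the control library and 68556 in the 4B4 library, a ratio of 2.08, and medians of 6368 and 8442 detected genes. Mitochondrially encoded genes took a median of 9.16% of a control cell's UMIs and 7.63% of a 4B4 cell's. With 1 library per group no difference has a replicate check, and library and treatment cannot be told apart. Levels are UMIs summed over the kept cells of a library per 1000000 of its UMIs (UPM), and all intervals are exact 95% intervals that cover counting error only.

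The series concerns the switch between mesenchymal and amoeboid invasion and its control by proteolysis, so the main comparison asks how transcripts differed when β1 integrin was blocked. Most genes had similar levels relative to the library totals: of the 6781 genes with at least 20 UPM in either library, 422 differed by at least 1.5-fold. Their median log2 ratio (4B4 over control) was -0.0027 over all 6781 genes, a value that division by library totals tends to hold near 0. Of the 6781 genes, 22 were at least 2-fold higher and 114 at least 2-fold lower in the 4B4 library. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, was at 23.2 UPM (22.3 to 24.0) in the control library and 107.5 (105.6 to 109.4) in the 4B4 library. SPP1, the secreted matrix protein osteopontin, was at 51.2 UPM (50.0 to 52.5) and 158 (156 to 161). SAA1, an acute-phase serum amyloid protein, had the largest ratio in the other direction, at 62.4 UPM (61.0 to 63.7) in the control library and 7.98 (7.47 to 8.51) in the 4B4 library. Its log2 ratio of -2.97 was -4.41 without the 1% of cells holding the most SAA1 in each library and -2.20 over G1 cells alone.

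The 12 largest ratios higher in the 4B4 library belonged to S100A9 (log2 ratio 2.44), UNC13C (2.28), HMOX1 (2.21), LINC01433 (2.06), SPP1 (1.63), IFITM1 (1.48), A4GALT (1.45), PRSS35 (1.39), HS6ST3 (1.35), CASC15 (1.30), CEMIP (1.28) and LINC01088 (1.28). S100A9, a calcium-binding protein best known from myeloid cells, was concentrated in few cells: 2051 of its 4307 UMIs in the 4B4 library came from 1 cell. Its log2 ratio was 3.24 under the stricter cell filter, 1.81 with each cell weighing the same and 1.38 over cells of 20000 to 60000 UMIs. Without the 1% of cells holding the most S100A9 in each library it was 2.62, at levels of 1.68 UPM and 10.3 UPM that lie below the floor of 20 UPM. CEMIP takes part in hyaluronan breakdown and A4GALT makes the glycolipid Gb3. At an equal depth of 17000 UMIs per cell, SPP1 was detected in 45.0% of control cells (43.3% to 46.8%) and 75.4% of 4B4 cells (73.0% to 77.7%), and HMOX1 in 22.6% (21.1% to 24.1%) and 51.0% (48.3% to 53.8%). Among all kept cells without thinning, these shares were 58.9% and 87.9% for SPP1 and 36.5% and 77.3% for HMOX1. Free RNA adds UMIs to cells that do not express a gene, and cultures of a single cell line hold no cell type that could serve as a background for these shares. The 12 largest ratios lower in the 4B4 library were those of SAA1 (-2.97), AURKB (-1.97), TENM2 (-1.95), GTSE1 (-1.93), PBK (-1.88), CDC20 (-1.86), BIRC5 (-1.82), TK1 (-1.79), DLGAP5 (-1.79), CCNB2 (-1.76), AMOTL2 (-1.76) and UBE2C (-1.75). Apart from SAA1, the adhesion protein gene TENM2 and the YAP target AMOTL2, these genes are best known from DNA synthesis or mitosis.

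**Figure D1:**
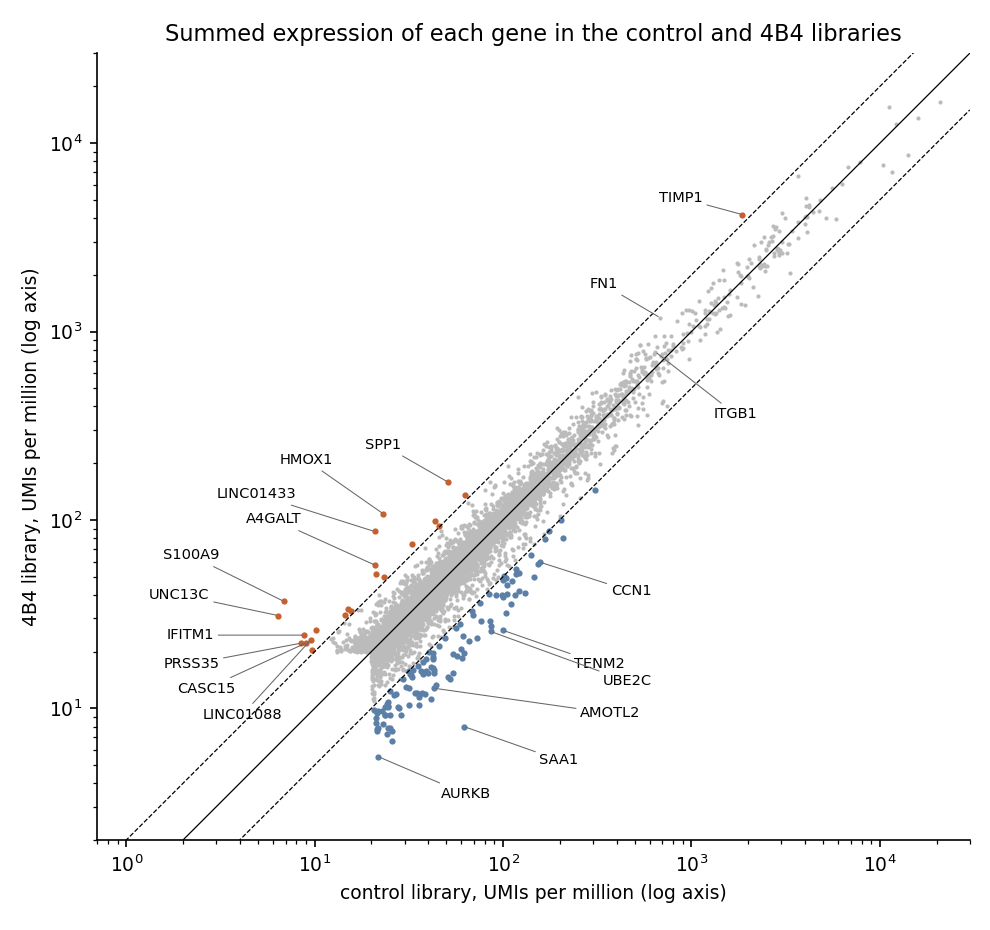
Level (UPM) of each gene with at least 20 UPM in either library, summed over kept cells, in the control library (horizontal, log axis) and the 4B4 library (vertical, log axis), with 1 library each. The solid line marks equality and the dashed lines a 2-fold difference; 22 genes lie above the upper dashed line (orange) and 114 below the lower one (blue).

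On the GRCh38 build, with positions from GENCODE release 29, HMOX1 (ENSG00000100292) lies on chromosome 22 from 35380361 to 35394214 and SPP1 (ENSG00000118785) on chromosome 4 from 87975650 to 87983426. SAA1 (ENSG00000173432) lies on chromosome 11 from 18266174 to 18269977, AMOTL2 (ENSG00000114019) on chromosome 3 from 134355874 to 134375479, and CCN1 (ENSG00000142871) on chromosome 1 from 85580761 to 85583962. TIMP1 (ENSG00000102265) lies on chromosome X from 47582313 to 47586789 and ITGB1 (ENSG00000150093), which encodes the subunit the antibody binds, on chromosome 10 from 32900319 to 33005792. UMIs were counted per gene, so no exon, intron or UTR is attached to these values.

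Genes of the cell cycle were lower in the 4B4 library. Of 53 measured genes of G2 and mitosis, 46 were at least 1.5-fold lower and none was higher, with a median log2 ratio of -1.47. TOP2A, the DNA topoisomerase of dividing cells, and MKI67, the Ki-67 proliferation antigen, had log2 ratios of -1.55 and -1.54, and AURKB and CDC20, which act in chromosome segregation, had -1.97 and -1.86. Of 41 measured genes of S phase, 34 were lower and none was higher, with a median of -0.90, among them TYMS (-1.69), which makes thymidylate, and RRM2 (-1.37), a ribonucleotide reductase subunit. The medians of both lists lay below those of all 10000 random lists matched on expression. Phase calls from these genes at equal depth put 11.6% of 3099 control cells (10.5% to 12.7%) in S phase and 20.5% (19.1% to 21.99%) in G2M, against 5.49% of 1311 4B4 cells (4.32% to 6.87%) in S and 6.71% (5.42% to 8.21%) in G2M. Without thinning the S shares were 12.3% and 5.42% and the G2M shares 19.7% and 6.64%. Under the stricter cell filter (at least 2000 genes and at most 10% mitochondrial UMIs) the control S and G2M shares were 14.5% and 29.1%, and the 4B4 shares 5.75% and 8.29%, so the control value depends on that filter. Phases are ranges of a per-cell score and not cell types: 202 control cells (6.52%) and 40 4B4 cells (3.05%) lay within 0.05 of the bound between G1 and the other phases. G2M cells had median S scores of 0.0059 in the control library and -0.036 in the 4B4 library, and median G2M scores of 0.40 and 0.29. A contribution of free RNA from cycling cells to these scores was not measured and stays open.

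**Figure D2:**
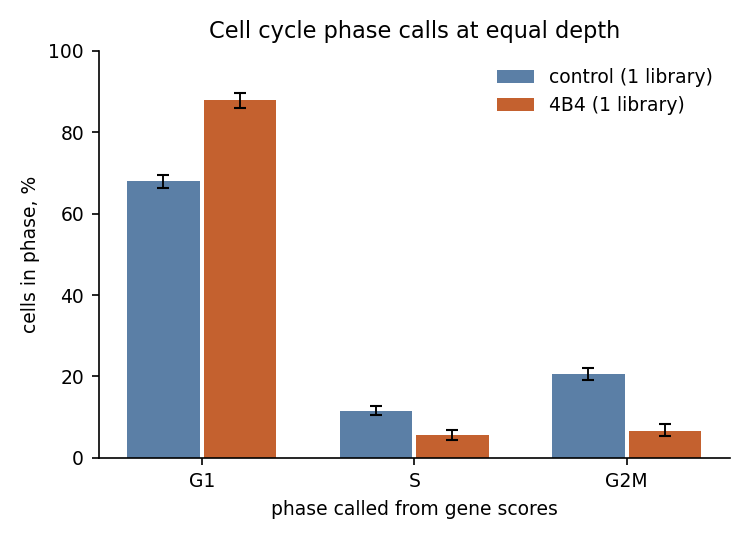
Share of cells (%, vertical) called G1, S or G2M from gene scores after thinning each cell to 17000 UMIs, in the control library (3099 cells) and the 4B4 library (1311 cells); error bars are exact 95% Clopper-Pearson intervals for counting error. G2M calls made up 20.5% of control cells and 6.71% of 4B4 cells.

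Part of the lower genes belonged to the cell cycle. Of the 114 genes at least 2-fold lower in the 4B4 library, 33 were on the S or G2M lists, and 39 were also at least 2-fold lower when only G1 cells were compared. Of the 22 higher genes, 16 were at least 2-fold higher among G1 cells too. With G1, S and G2M cells given the same weight in both libraries, 21 genes were at least 2-fold higher and 22 lower. The S and G2M weights then rested on 72 and 88 cells in the 4B4 library. Phases were called from cell cycle genes, which sets the ratios of such genes in part in both comparisons. The fall in lower genes thus does not measure the share due to the cell cycle.

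Targets of YAP and TEAD, transcriptional regulators that respond to adhesion, spreading and stiffness, were lower in the 4B4 library. Of 20 measured targets, 13 were at least 1.5-fold lower and none was higher, with a median log2 ratio of -0.76 that lay below all 10000 random lists. AMOTL2 was at 43.1 UPM (42.0 to 44.3) in the control library and 12.8 (12.1 to 13.4) in the 4B4 library, and ANKRD1 at 116 (114 to 118) and 39.8 (38.7 to 41.0). CCN1, a matricellular protein, was at 157 UPM (155 to 159) and 59.6 (58.2 to 61.1). AJUBA, a LIM-domain scaffold protein, had a log2 ratio of -1.29. Over G1 cells alone the list's median was -0.73. Targets of SRF and MRTF, which follow the state of actin, had a median of -0.18 at percentile 0.030 of random lists, with 6 of 20 measured genes lower and none higher. Its members with the largest ratios were FHL2 (-1.01), TAGLN (-0.99), CNN3 (-0.87) and FILIP1L (-0.83). The median was -0.10 over G1 cells and -0.28 under the stricter filter, and over cells of 20000 to 60000 UMIs TAGLN (-0.51) and FILIP1L (-0.43) came below 1.5-fold.

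Adhesion and lamellipodium genes showed small differences as groups. Of 13 measured integrin subunits, ITGA11, a collagen receptor subunit, was higher (log2 ratio 0.62) and ITGA6, a laminin receptor subunit, was lower (-0.81), and the median of 0.049 lay at percentile 74.2. ITGA11 came below 1.5-fold over G1 cells (0.39) and ITGA6 with phases weighing the same (-0.53). ITGB1 itself was at 642 UPM (638 to 647) in the control library and 780 (775 to 785) in the 4B4 library, a log2 ratio of 0.28. ITGA2 had 0.27, ITGA5 0.14 and ITGAV -0.10. The sign of the ITGA5 and ITGAV ratios turned under other settings. ITGB8 had -0.56 and ITGA1, also a collagen receptor subunit, -0.54, short of 1.5-fold but below 0 under every setting for ratios. Over G1 cells alone the integrin median was -0.15, at percentile 0.50. Of 30 focal adhesion genes, CAV1, the main caveolar coat protein, was lower (-1.22) and none was higher. The median of -0.11 lay at percentile 1.40, and at 12.8 at most under other settings, 5 of which took it inside the central range. VCL, which encodes vinculin, had a log2 ratio of -0.35. Among single cytoskeleton genes, MYLK (-1.18), the kinase of myosin light chain, DIAPH3 (-1.34) and ECT2 (-1.05) were lower, and MYL9 had 0.13. ECT2 is also on the G2M list, and DIAPH3 had a ratio of 0.11 with phases weighing the same. None of the 31 measured genes of Rac, Arp2/3 and the lamellipodium passed a 1.5-fold difference, and their median of 0.0093 lay at percentile 51.2. TIAM1, a Rac activator, had a log2 ratio of -0.58 and CTTN, which encodes cortactin, 0.38.

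Proteases and their inhibitors differed gene by gene. Of 17 matrix metalloproteinases, 5 were measured, and MMP14, the membrane-bound collagenase MT1-MMP, was higher, at 40.4 UPM (39.3 to 41.6) in the control library and 61.8 (60.4 to 63.3) in the 4B4 library. Its log2 ratio of 0.61 came below the 1.5-fold bound under 5 of 12 other settings, at 0.55 over G1 cells. MMP2, the gelatinase that MMP14 activates, had a log2 ratio of -0.0054, MMP16 -0.011, MMP17 0.34 and MMP24 -0.092; the median of -0.0054 lay at percentile 52.9. MMP1 and MMP9 were below the floor of 5 UPM in both libraries, as were ITGB3 and COL1A1. TIMP1, a secreted metalloproteinase inhibitor, was at 1861 UPM (1853 to 1868) in the control library and 4176 (4165 to 4188) in the 4B4 library, a ratio of 2.24. SERPINB2 was lower (-0.68, but -0.15 over cells of 20000 to 60000 UMIs) and TIMP2 had a log2 ratio of 0.16; the 11 measured inhibitors had a median of 0.15 at percentile 95.5. Both plasminogen activators were lower: PLAU, the urokinase type, was at 202 UPM (199 to 204) and 100.3 (98.49 to 102.1), and PLAT, the tissue type, had a log2 ratio of -1.08. PLAUR, the receptor gene of the urokinase type, had 0.33. HTRA1 (0.85), a secreted serine protease, and FURIN (0.67), a proprotein convertase, were higher. FURIN had 0.48 over cells of 20000 to 60000 UMIs and PLAU -0.58 with phases weighing the same, below 1.5-fold. The 17 measured proteases outside the metalloproteinases had a median of 0.092 at percentile 92.2, and lay above the central 95% of random lists under 6 of 13 other settings.

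**Figure D3:**
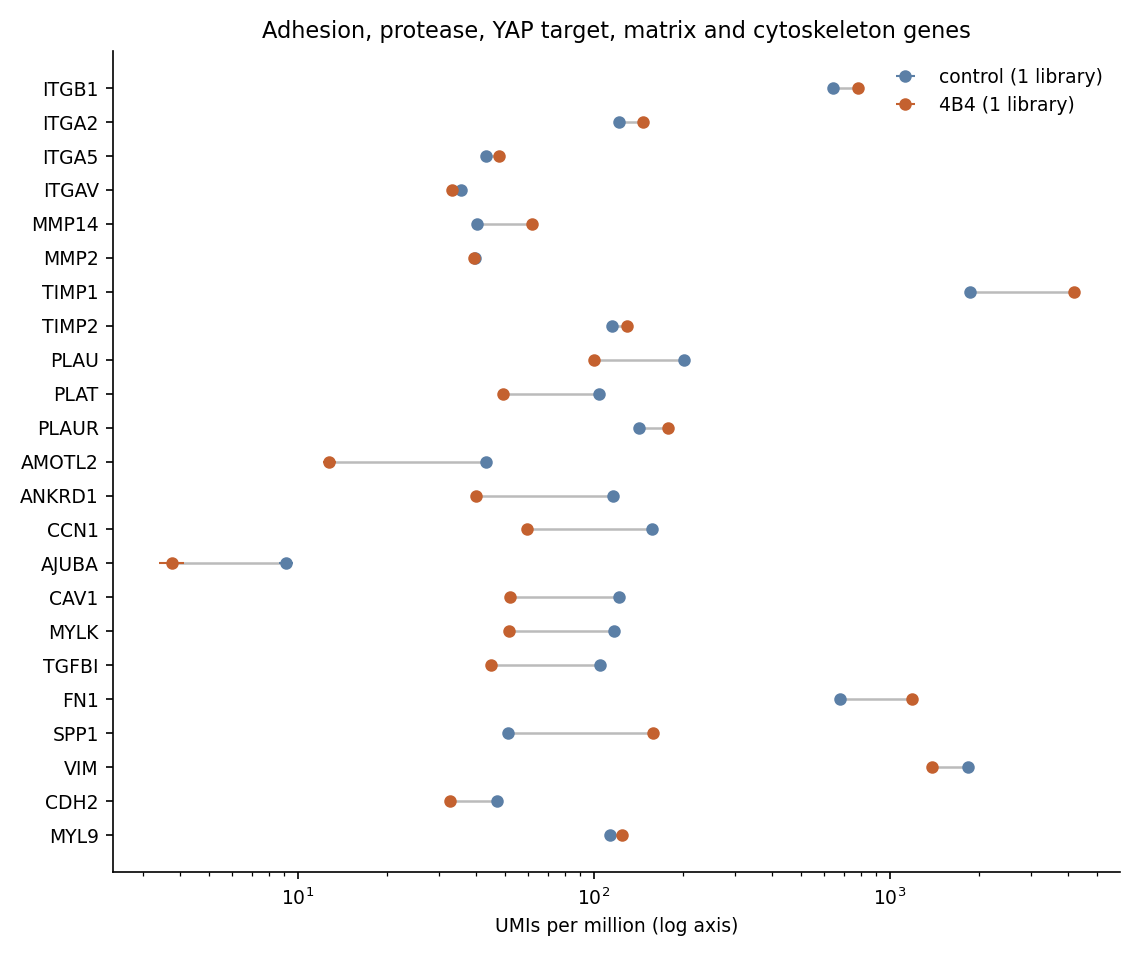
Level (UPM, log axis) of selected adhesion, protease, YAP target, matrix and cytoskeleton genes in the control (blue) and 4B4 (orange) libraries, 1 library each; horizontal bars, mostly narrower than the points, are exact 95% Poisson intervals. TIMP1 lies at 1861 and 4176, PLAU at 202 and 100.3, and AMOTL2 at 43.1 and 12.8.

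Matrix genes differed in both directions. FN1, which encodes fibronectin, was at 681 UPM (676 to 685) in the control library and 1185 (1179 to 1191) in the 4B4 library, and SPP1 and MGP (1.24) were also higher. MGP was low, at 2.22 UPM in the control library and 5.25 in the 4B4 library, where 13 cells held 43.9% of its UMIs. Without the 1% of cells holding the most MGP in each library its log2 ratio was 1.16. Its levels were then 1.34 and 2.99 UPM, below the floor for measured members. Over G1 cells FN1 had a log2 ratio of 0.52, below 1.5-fold. CCN1 (-1.39) and TGFBI (-1.22) were lower. In all 4 of 28 measured matrix proteins outside the collagens were higher and 4 lower, with a median of 0.032 at percentile 78.5. Collagen and collagen-processing genes had a median of 0.15 at percentile 99.6, with 1 of 23 higher and 2 lower: COL7A1 (0.73) was higher, and COL12A1 (-0.80) and COL13A1, at 31.7 UPM (30.7 to 32.7) and 15.8 (15.1 to 16.5), were lower, so the 2 largest ratios went against the median. TGF-beta response genes had a median of 0.33 at percentile 100, with 3 of 21 higher and 2 lower, and one of 0.19 without the gene length trend. PMEPA1 (1.07), a feedback inhibitor, and LTBP3 (0.90), which binds latent TGF-beta, were higher, and TGFBI (-1.22) and TGFB2 (-1.06) were lower. Mesenchymal genes and transition factors had a median of -0.14 at percentile 2.26, a value that stayed below percentile 2.5 under 7 of 13 other settings. VIM, which encodes vimentin, had a log2 ratio of -0.39 and CDH2, which encodes N-cadherin, -0.53, and AXL, a receptor kinase also counted as a YAP target, was lower (-0.89). The transcription factors FOXC2 (1.19), SNAI1 (0.74) and TWIST1 (0.70) were higher.

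**Figure D4:**
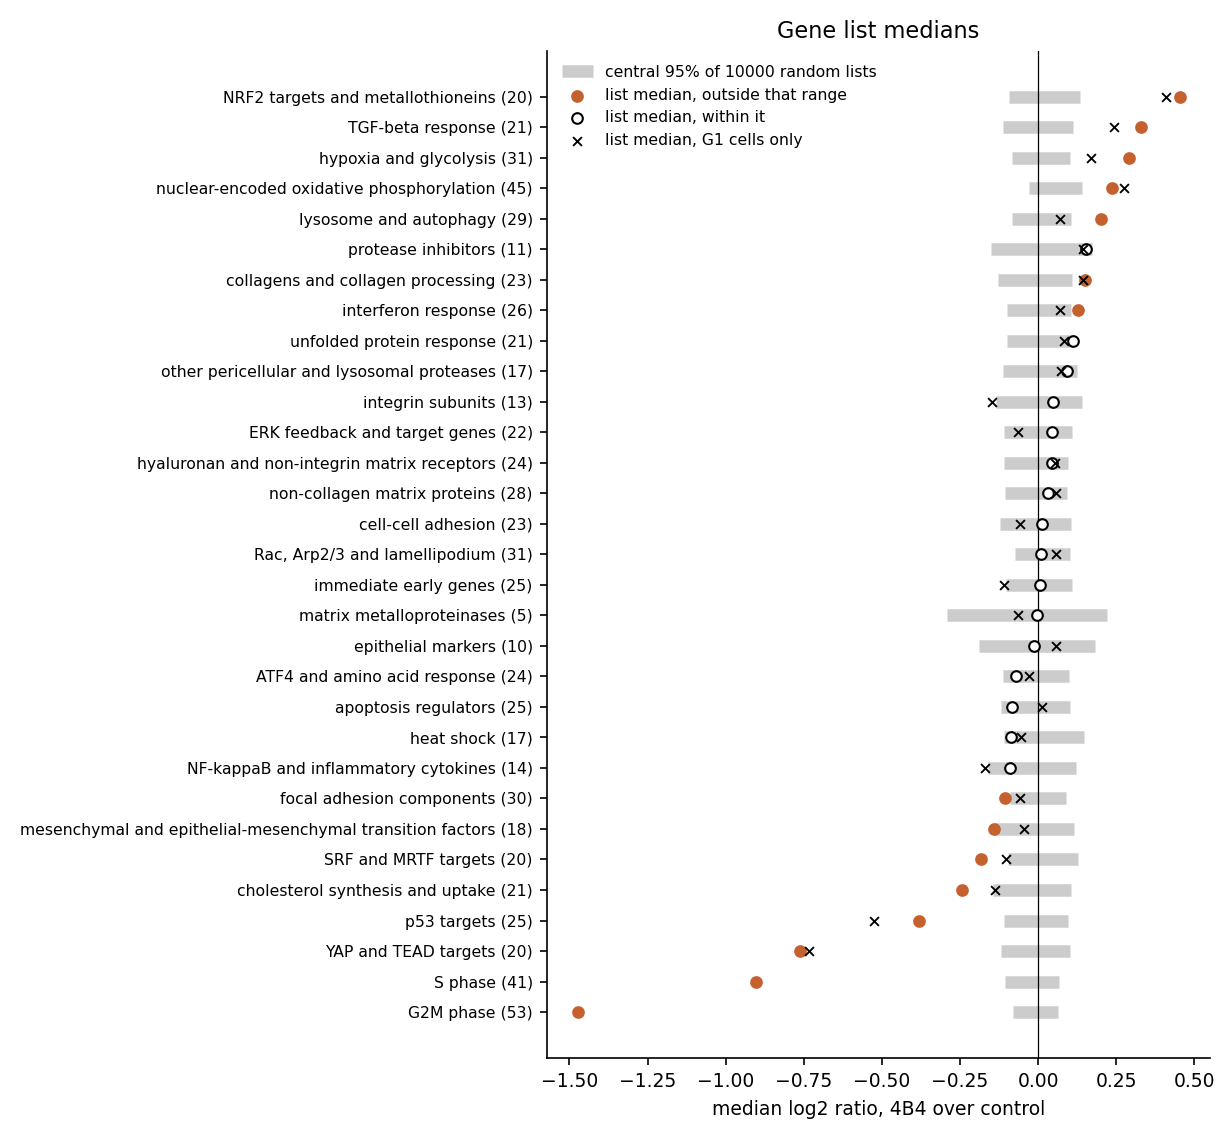
Median log2 ratio (4B4 over control, horizontal) of the gene lists described, with the number of measured members in brackets; grey bars span the central 95% of medians of 10000 random lists matched on expression, and crosses give the median over G1 cells only, except for the S and G2M lists, whose genes set the phases. The G2M list lies at -1.47, and the YAP and TEAD targets at -0.76 over all cells and -0.73 over G1 cells.

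Cells of the libraries were partly separated in expression space. With 1311 cells drawn from each library at equal depth, on average 77.6% of a cell's 15 nearest neighbours came from its own library, and 78.9% without cell cycle genes and genes correlated with their scores. Random splits of the control and 4B4 cells gave 50.2% and 49.4%. Such splits mix cells of the same library by design, so they give no baseline for the separation of different libraries. Clustered alone, the control library had 3 clusters and the 4B4 library 5. Cluster 3 of the control library and cluster 2 of the 4B4 library had the mitotic genes DLGAP5 and MKI67 among their leading genes. Their profiles, centred within each library, had a rank correlation of 0.787 across 6562 genes, which are not independent replicates. Clusters with LRRTM4 and SGO1-AS1 among their leading genes (cluster 2 of the control library and cluster 5 of the 4B4 library) had a correlation of 0.930. They held 24020 and 31460 UPM of MALAT1, a nuclear RNA, against 5353 to 7267 UPM in the other control clusters and 1634 to 22940 UPM in the other 4B4 clusters. Their median mitochondrial shares, 10.1% and 8.50%, were the highest among the clusters of each library. Cluster 1 of the control library, led by APOE and APOC1, matched clusters 1 (0.922) and 4 (0.911) of the 4B4 library, which were led by IL11 and S100A9. APOE and APOC1 were also among the leading genes of cluster 4 of the 4B4 library. S100A9 was concentrated in few cells, and whether these set its lead in that cluster was not tested. Cluster 3 of the 4B4 library, led by ANKRD1, was nearest to cluster 2 of the control library (0.835). No cell types were assigned within this cell line.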

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

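Of the tests below, those over cells of 20000 to 60000 UMIs and with control G2M UMIs drawn down were chosen after the data had been seen. Barcodes left out of the comparisons differed between the libraries. Of the 1759 barcodes of the 4B4 library, 250 (14.21%, 12.6% to 15.9%) had over 50% of their UMIs from mitochondrially encoded genes, against 172 of 3642 (4.72%, 4.06% to 5.46%) in the control library. This is a signal in data outside the main comparison, above its level in the control sample. In all, 21.3% of 4B4 barcodes and 6.59% of control barcodes were left out, with medians of 4406.5 and 2572 UMIs. The cause was not tested, and a difference in handling, viability or cell calling between the libraries stays open.

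Genes of the cell cycle were lower in the 4B4 library, with a G2M median of -1.47. Over cells of 20000 to 60000 UMIs the median was -2.30. That range held 71.2% of control G2M cells and 17.0% of 4B4 G2M cells and so overstates the gap. It therefore cannot test a difference in UMIs per cell. With every cell at equal depth the median was -1.42, which argues against the weight of deeper cells in the sums as the source. Thinning keeps each cell's expected proportions, so it cannot test other effects of UMIs per cell. G2M genes took 0.696 times (0.667 to 0.727) the share of non-mitochondrial UMIs in 4B4 barcodes left out as in those kept. The RNA in the barcodes left out thus held no excess of G2M genes. These barcodes had medians of 82.7% mitochondrial UMIs and 477 detected genes, so their remaining RNA may not show which cells had been cycling. Loss of cycling cells to the quality filter is therefore not excluded. A lower level within cycling cells is argued against as the whole difference, since within G2M cells called from a part of the list the other part had a median of -0.22 (quartiles -0.31 and -0.12), against -1.55 over all cells, where control cells with G2M UMIs drawn down to the overall ratio gave -0.85. Fewer cycling cells in the 4B4 culture may lie behind the pattern, as a hypothesis found and tested on the same data. Selective loss of cycling cells before capture or to the quality filter stays open. So do effects of UMIs per cell beyond the weight of deeper cells, and a difference between the cultures unrelated to the antibody.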

How the results depend on the processing

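The medians of YAP and TEAD targets, SRF and MRTF targets, collagens and TGF-beta response genes kept their sign and stayed apart from random lists under all 13 other settings, though some moved by over 1.5 times. The SRF and MRTF median was -0.28 and the TGF-beta median 0.20 under the stricter filter, -0.10 for the first over G1 cells and 0.19 for the second without the length trend. The collagen median was 0.25 with each cell and 0.23 with each phase weighing the same, and 0.24 at 20000 to 60000 UMIs. G1 cells only, 20000 to 60000 UMIs per cell, removal of the gene length trend and leaving out the top 1% of cells were chosen after seeing the data. Of 153 named genes, 142 kept their sign under all 12 ratio settings. The 12 largest ratios each way were chosen for this, and list members for their large ratios. A kept sign under settings that reuse the same libraries thus tests little. The total UMIs of each library are no limit for summed counts, though effects of the difference in UMIs per cell stay open. A limit is 1 library per group: no replicate could be left out and no paired analysis run. Doublet calls moved almost nothing.

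Genes at least 2-fold higher numbered 45 with each cell weighing the same, and 43 and 10 at floors of 5 and 50 UPM, and 122 passed 1.5-fold. Genes at least 2-fold lower numbered 185 under the stricter filter, 71 with each cell weighing the same, 22 with phases weighing the same, 45 over G1 cells, and 250 and 49 at those floors, and 300 passed 1.5-fold. The floors and the 1.5-fold bound change by construction how many genes can be counted; otherwise the cause was not tested.

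The proteases outside the metalloproteinases came to stand apart without a cell filter (0.13), in thinned cells (0.20), with each cell (0.21) or phase (0.21) weighing the same, at 20000 to 60000 UMIs (0.16) and without the length trend (0.16). Protease inhibitors did so at 20000 to 60000 UMIs (0.26) and other matrix proteins in thinned cells (0.14). Integrin subunits turned to -0.15 over G1 cells. Focal adhesion genes no longer stood apart under the stricter filter (-0.12), with each cell weighing the same (-0.024), over G1 cells (-0.057) and without the length trend (-0.061), and had 0.0048 with phases weighing the same. Mesenchymal genes no longer stood apart without a cell filter (-0.11), in thinned cells (-0.090), with each cell (-0.044) or phase (-0.057) weighing the same, over G1 cells (-0.046) and without the length trend (-0.088). The unfolded protein response came to stand apart in thinned cells (0.17), with each cell (0.15) or phase (0.14) weighing the same and at 20000 to 60000 UMIs (0.27). NF-kappaB genes did so at 20000 to 60000 UMIs (-0.32) and over G1 cells (-0.17), the ATF4 response with phases weighing the same (-0.044) and heat shock without a cell filter (-0.11). Immediate early genes turned to -0.11 over G1 cells and to -0.11 without the length trend. The cause was not tested.

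With each cell weighing the same, the ratios of BTG2 (0.060), ITGAV (0.0018) and MTHFD2 (0.0087) were above 0. With phases weighing the same, those of DIAPH3 (0.11), ITGAV (0.039) and NCAM1 (0.026) were. Some genes called higher or lower came below 1.5-fold under other settings, among them UQCRQ (0.44) at 20000 to 60000 UMIs, VEGFA (0.42) and RRM2 (-0.092) over G1 cells, ECT2 (-0.11) with phases weighing the same, MMP14 without the length trend (0.55), in thinned cells (0.56), with phases weighing the same (0.58) and over a total without mitochondrial and ribosomal protein genes (0.57), IRF1 (-0.29) and PLK2 (-0.50) with each cell weighing the same, and IL11 (0.43) under the stricter filter. The cell cycle genes among the 12 largest lower ratios ranged from AURKB (-0.58) to DLGAP5 (-0.29) with phases weighing the same, which phase calls made from such genes set in part. ITGA5 had -0.015 at 20000 to 60000 UMIs and SDF2L1 0.033 over G1 cells. The own-library share of neighbours was 74.4% with 1000 variable genes and 75.5% with 30 neighbours. At Leiden resolution 1 each library had 9 clusters, and at 0.3 the 4B4 library had 3. Under the stricter filter control cells in S and G2M made up 14.5% and 29.1%, and 4B4 cells in G2M 8.29%.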

Other observations

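Of the tests below, those over G1 cells, over cells of 20000 to 60000 UMIs and with the gene length trend removed use settings chosen after the data had been seen, and those of few cells holding most UMIs and of a small subset of cells were chosen after the result was seen. Of the metabolic and stress lists outside the main ones, some had medians above random lists and others below. Of 20 measured NRF2 targets and metallothioneins, which answer oxidative and metal stress, 9 were at least 1.5-fold higher and 1 lower, with a median log2 ratio of 0.45 at percentile 100. HMOX1 (2.21), ME1 (0.90), the ferritin gene FTH1 (0.87) and the cystine transporter gene SLC7A11 (0.84) had the largest ratios. Hypoxia and glycolysis genes had a median of 0.29 (2 of 31 higher, none lower), with VEGFA at 0.64. Nuclear-encoded genes of oxidative phosphorylation had 0.24 (2 of 45 higher, none lower), with UQCRQ at 0.68, and lysosome and autophagy genes 0.20 (none of 29 past 1.5-fold), with GABARAP at 0.57. All 3 medians lay at percentile 100; over G1 cells that of lysosome genes was 0.069, at percentile 85.4, and that of hypoxia genes 0.17, and with each cell weighing the same that of oxidative phosphorylation genes was 0.15. Mitochondrially encoded genes took 8.97% of UMIs in the control library and 6.55% in the 4B4 library.

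Targets of p53 had a median of -0.38 (-0.24 with each cell weighing the same), at percentile 0, with 7 of 25 lower and none higher, among them PLK2 (-1.53, and -0.50 with each cell weighing the same), MDM2 (-0.86), which encodes the ligase that limits p53, and FDXR (-0.80). Cholesterol synthesis and uptake genes had -0.24 at percentile 0.11 over 21 genes, with STARD4 at -0.48 and ACAT2 at -0.45; the median was -0.14 over G1 cells and -0.099 with each cell weighing the same. Interferon response genes had 0.13 at percentile 98.9 (3 of 26 higher, 1 lower), with IFITM1 at 1.48 and IRF1 at -0.64, and stood apart under 6 of 13 other settings. The remaining lists lay within the central 95% of random lists over all kept cells, that of the unfolded protein response at percentile 97.49. Under other settings the unfolded protein response stood apart in 4 of 13, NF-kappaB and immediate early genes in 2 each, and ATF4 and heat shock in 1 each. Their medians were 0.11 for the unfolded protein response (none of 21 past 1.5-fold), -0.087 for heat shock (none of 17), -0.071 for the ATF4 and amino acid response (3 of 24 higher, 1 lower) and -0.089 for NF-kappaB and inflammatory cytokines (2 of 14 higher, 1 lower). They were 0.045 for ERK targets (1 of 22 higher, 4 lower), 0.0047 for immediate early genes (1 of 25 higher, 5 lower) and -0.086 for apoptosis regulators (1 of 25 higher, 2 lower). They were -0.013 for epithelial markers (none of 10), 0.011 for cell-cell adhesion (none of 23 higher, 2 lower) and 0.043 for hyaluronan and other matrix receptors (2 of 24 higher, 2 lower). Within the inflammatory list IL1B (1.19) was higher and RELB (-0.74) lower.

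Of 61 markers of other cell types, 36 were below 1 UPM in each library. KRT8, KRT10, KRT18 and TNNT1 were above 100 UPM in both and so mark no other cell type here. Among leukocyte markers CD68 was at 26.5 UPM in the control library and 38.4 in the 4B4 library, CD3D at 4.63 and 3.38 and PTPRC at 0.786 and 0.799. The cell with 2051 S100A9 UMIs also held 139 of the 142 S100A8 UMIs of the 4B4 library. It had 192465 UMIs in all, 7 of the 100 CD14 UMIs of the library, 21 UMIs of CD68, 0 of PTPRC, LYZ and TYROBP, and 724 of TIMP1. Genes with long spans were slightly lower in the 4B4 library: the median log2 ratio was 0.072 over genes with spans up to 14020 bp and -0.067 over genes with spans of at least 101489 bp, with a rank correlation of -0.23 across 6772 genes, which are not independent.

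YAP and TEAD targets had a median of -0.76. Fewer cycling cells as the source are argued against by a median of -0.73 over G1 cells alone, and a trend with gene length by -0.69 after its removal. Over cells of 20000 to 60000 UMIs the median was -0.69. Median depths in that range were 33702 UMIs in 2449 control cells and 43835 UMIs in 502 4B4 cells. The range thus narrows the gap in depth without removing it and takes different parts of the libraries. A difference in UMIs per cell is therefore only partly tested. Blocked β1 integrin signalling may lie behind the pattern, as a hypothesis. It cannot be told apart from other effects of adding an antibody, as the control's treatment label names none. The target ANKRD1 was not uniform across 4B4 cells: it was at 84.6 UPM in cluster 3 and 27.0 UPM in the other 4B4 cells. Whether the shares of such cells differed between the libraries was not tested. A difference in cell density, in dissociation or between the libraries was not tested and stays open, and 1 library per group cannot exclude it.

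The 12 largest ratios higher in the 4B4 library had a median of 1.47. It was 1.585 under the stricter filter and 1.47 over cells of 20000 to 60000 UMIs, but these genes were chosen for keeping their sign under such settings, so damaged cells and a difference in UMIs per cell stay open. The 1% of 4B4 cells holding the most of a gene held a median of 13.3% of its UMIs, which argues against so few cells as the holders of most UMIs of the group, though not for S100A9 (72.4%) and less so for HS6ST3 (38.4%). Shares of cells with a UMI at equal depth had a median ratio of 2.10, with S100A9 in 9.08% of 4B4 cells and 3.32% of control cells. Free RNA was not measured and could spread UMIs over many cells, so a larger subset of cells as the source stays open, as do differences between the libraries and a response to the antibody.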
